A study of Mus musculus with 18 samples.

How the data were processed

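DNA methylation was profiled by methylated DNA immunoprecipitation (MeDIP), in which an antibody against methylated cytosine pulls down fragmented genomic DNA, and histone methylation by chromatin immunoprecipitation (ChIP) with antibodies named H3K4 and H3K9 in the labels, which do not give the number of methyl groups. The material came from C57BL/6 mice. Per the labels, each of the 18 arrays was hybridised with the immunoprecipitate in Cy3 and the input DNA of the same tissue in Cy5, with no dye swap. The MeDIP arrays covered cerebellum (3 biological replicates and 2 technical replicates), heart (3) and sperm (2), and each antibody had 2 arrays in cerebellum and 2 in heart.

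The deposited values are 1 log ratio per probe and array, for 99079 probes, taken here as log2. The scanned images were processed with Agilent Feature Extraction, per the submitters' processing notes, which give no version. The base of the logarithm, the channel in the numerator, the background correction, the dye normalization and the genome build are not given in the sources used here. Base 2 was taken because the most extreme ratios would exceed the range of a 16-bit scanner in the other usual bases, an argument that fails where processed signals lie below 1. The mean of each array was close to 0, by a step not given in the sources used here, and the medians lay between -0.050 and 0.15. The spread had not been made equal, with standard deviations from 0.75 to 1.38. No value was missing and none was exactly 0. Single-channel intensities were not used here, so signal over background is unknown and the number of arrays limits the precision.

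Each array was centred on its median, with no loess or quantile step, because many probes of such an array can shift in one direction. Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with Benjamini-Hochberg adjustment over all 99079 probes and a threshold of 0.05 on the adjusted p. The MeDIP model held the 8 arrays called biological replicates. The 2 technical arrays stayed out of it because the labels do not say which cerebellum sample they repeat. The ChIP model held all 8 ChIP arrays, so that the 4 groups of 2 arrays shared 1 estimate of the spread. The labels call the arrays biological replicates but do not say that they came from separate animals, so the p-values measure the spread between these samples, which may be technical.

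These tests, the samples in each, the alternatives (deposited centring, quantile normalization, equal spread, a replicate block, leaving out each array, another variance model, only the groups compared, the technical arrays added as 1 sample, and a minimum difference of 1) and the rule for named features were chosen before the data were examined. Everything that uses windows or the order of probe IDs was chosen after the data were examined. No table used here pairs the probes with positions or genes, so the means over genes, promoters and imprinted control regions that had been planned were not run, and probes are named by ID. In that case the rule names, per comparison, at most 2 probes with a higher and 2 with a lower ratio. They are those with the largest difference among probes past the threshold for which every array of one group lay on the same side of every array of the other.

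Windows were non-overlapping runs of 5 probes in ID order with ID steps of at most 5, which gave 16650 windows holding 83250 probes. Window means per array were tested with limma in the same models. Called windows that followed each other directly were counted as 1 cluster. Long ID blocks were runs of at least 600 probes with no ID step above 1000, restricted to the high ID numbers, where 11 such blocks held 47710 probes; the other 51369 probes, lower-numbered long runs included, were treated together as other IDs. Mean ratios and overlaps at windows were tested two-sided against 10000 circular shifts along the ID order, with long blocks and other IDs shifted separately, for which the smallest p is 0.0001. In a circular-shift permutation test the unit is the place along the array, so its p describes these arrays and not the spread between samples.

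Arrays of different groups share replicate numbers. The deviations of same-numbered ChIP arrays from their group means correlated across probes between 0.16 and 0.32 in 12 of 12 pairs. In a group of 2 arrays the deviations mirror each other, so each value occurs for both numbers and the 12 pairs are not independent. With 2 arrays per group, the 4 groups line up in this way by chance in 1 of 8 cases. The ChIP numbers may therefore pair the samples, but the main ChIP fits have no block. Counts of ChIP differences between tissues are also given with the replicate number as a block where this moved them. The MeDIP numbers were not treated as pairing, so a block in the calling of MeDIP windows is an alternative only.

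The procedure was tested on simulated data with the spread of the real arrays, in which 200 features were changed. Noise was drawn independently for each feature and array, without the correlation of same-numbered ChIP arrays. The estimated spread of each feature was taken as its true spread. The recovery holds for that setting and may differ in the real arrays. Of the features changed by 2 on the log2 scale, limma on single probes recovered 37.3% for MeDIP in cerebellum against heart, 32.8% for somatic tissues against sperm, 13.4% for cerebellum against sperm and 8.96% for heart against sperm. It recovered 0% for H3K4 and 0% for H3K9, at a change of 3 as well. On windows the recovery at a change of 2 was 98.5%, 91.0%, 82.1% and 94.0% for the 4 MeDIP comparisons, 82.1% for H3K4 and 79.1% for H3K9. At a change of 1 it was 50.7%, 47.8%, 44.8% and 37.3% for MeDIP, 25.4% for H3K4 and 23.9% for H3K9. Single probes changed by 1 were recovered in 0% in every comparison. Unchanged features were called 0 to 4 times on probes and 5 to 11 times on windows.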

Results

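The series measured DNA and histone methylation on tiling arrays in mouse tissues, with the stated purpose of finding imprinted control regions, the short stretches whose methylation differs between the parental copies and is set in the germ line, by comparing sperm, heart and cerebellum. The MeDIP arrays comprised 3 cerebellum, 3 heart and 2 sperm samples and 2 technical replicates of cerebellum. The ChIP arrays comprised 2 samples each of H3K4 and H3K9 in cerebellum and in heart. Every array gave a log2 ratio for 99079 probes.

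Which channel was the numerator is not settled, so higher and lower refer to the deposited ratio and not to more or less methylation. The H3K4 arrays had a longer right tail (skew 0.23 to 0.76, 99th percentile 2.34 to 3.16 and 1st percentile -2.37 to -1.92), the side on which a mark limited to few places lies when the immunoprecipitate is the numerator. The MeDIP arrays (skew -0.72 to -0.22) and the H3K9 arrays (skew -0.67 to -0.084) had longer left tails, and the usual Feature Extraction ratio, Cy5 over Cy3, would put the input in the numerator. If the ratio is input over immunoprecipitate, the differences between groups change sign together, whereas a share or overlap of the top 10% becomes that of the bottom 10%, which is given separately.

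Replicate arrays correlated across probes with Pearson r of 0.79 to 0.83 in cerebellum MeDIP, 0.81 to 0.84 in heart MeDIP and 0.83 in sperm MeDIP. MeDIP samples of different tissues overlapped with these values, from 0.69 (sperm 1 with heart 3) to 0.84 (cerebellum 2 with sperm 2). On this measure the arrays do not separate by tissue. The ChIP pairs were lower, at 0.64 and 0.66 for H3K4 and 0.62 and 0.64 for H3K9 in cerebellum and heart. Probes are not independent replicates, and the correlations describe agreement only. Probes with consecutive IDs had similar differences between tissues, whereas randomly paired probes did not, and 5 such probes were therefore averaged into windows. The correlation of the somatic minus sperm MeDIP difference was 0.42 over 79657 pairs of consecutive IDs and 0.029 over 7856 pairs at an ID step of 20. It did not fall smoothly beyond that. At a step of 50, where uninterrupted IDs left 1168 pairs, it was -0.14, and for H3K4 cerebellum minus heart it was 0.46, as high as between consecutive IDs.

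**Figure D1:**
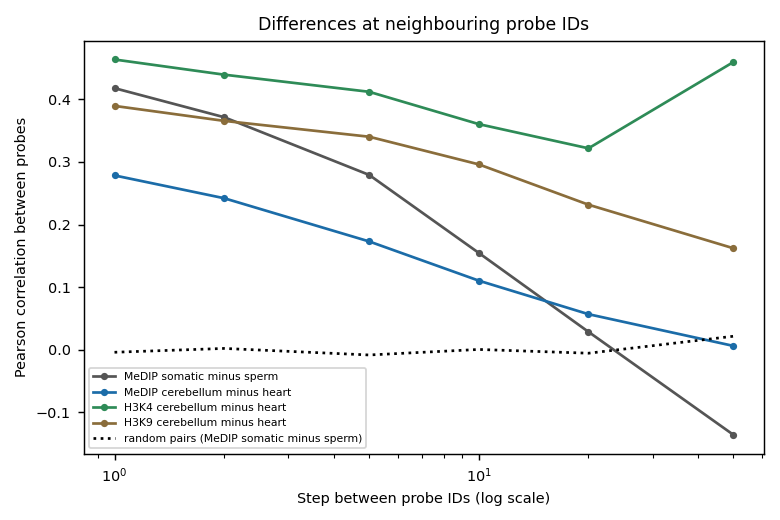
Pearson correlation between the differences at probes a given ID step apart (x axis, log scale) for 4 comparisons, with randomly paired probes as a dotted line. The MeDIP somatic minus sperm correlation falls from 0.42 at a step of 1 to 0.029 at a step of 20, and to -0.14 at 50, while H3K4 is at 0.32 and 0.46 at those steps.

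The comparison of somatic tissues with sperm addresses which places carry a different MeDIP ratio in the male germ line. Of 16650 windows, 294 had a higher ratio in the somatic tissues than in sperm and 129 a lower one (limma, adjusted p under 0.05). At the 294 windows the mean ratio was 0.85 ± 0.19 (SD, n = 3) in cerebellum, 0.70 ± 0.26 (n = 3) in heart and -0.57 ± 0.037 (n = 2) in sperm. At the 129 windows it was -0.064 ± 0.066 in cerebellum, 0.077 ± 0.080 in heart and 1.01 ± 0.085 in sperm. The median differences were 1.22 and -0.94. The higher windows formed 199 clusters and the lower windows 101 clusters of adjoining windows. All 11 long ID blocks held higher windows and 8 held lower ones. The share of windows with a higher ratio was 1.77% over all windows. Over the long blocks it ran from 0.79% in block 8 to 6.38% in block 5, with 5.26% in block 1 and 6.11% in block 11. Blocks 1, 5 and 11 held only 8, 9 and 8 such windows. Lower windows outnumbered higher ones in block 8 (26 against 11), block 9 (15 against 6) and block 7 (9 against 8). With the arrays scaled to one spread the counts were 572 and 489 and with quantile normalization 684 and 351. Without sperm 1, sperm 2 or heart 3 the totals were 91, 60 and 259 in place of 423.

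Among single probes, 725 of 99079 differed between somatic tissues and sperm, 611 higher and 114 lower, by 1.31 to 4.12 in size. Probe A_68_P24333850 had the largest higher ratio (3.88, SE 0.39, limma adjusted p = 0.0024), with 1.67 ± 0.42 in cerebellum and -2.29 ± 0.71 in sperm. The neighbouring ID A_68_P24333851 followed with 3.80. The largest lower ratios were at A_68_P28738454 (-4.12, SE 0.44, limma adjusted p = 0.0024), where sperm reached 2.19 ± 0.21 against -2.19 ± 0.35 in cerebellum, and at A_68_P10147998 (-3.96). No probe passed without sperm 1 or without sperm 2, a setting in which the lone sperm array is assumed to vary like the other groups. The count was 403 without cerebellum 2, 414 without heart 3, 1272 with the arrays scaled to one spread and 1472 with quantile normalization.

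**Figure D2:**
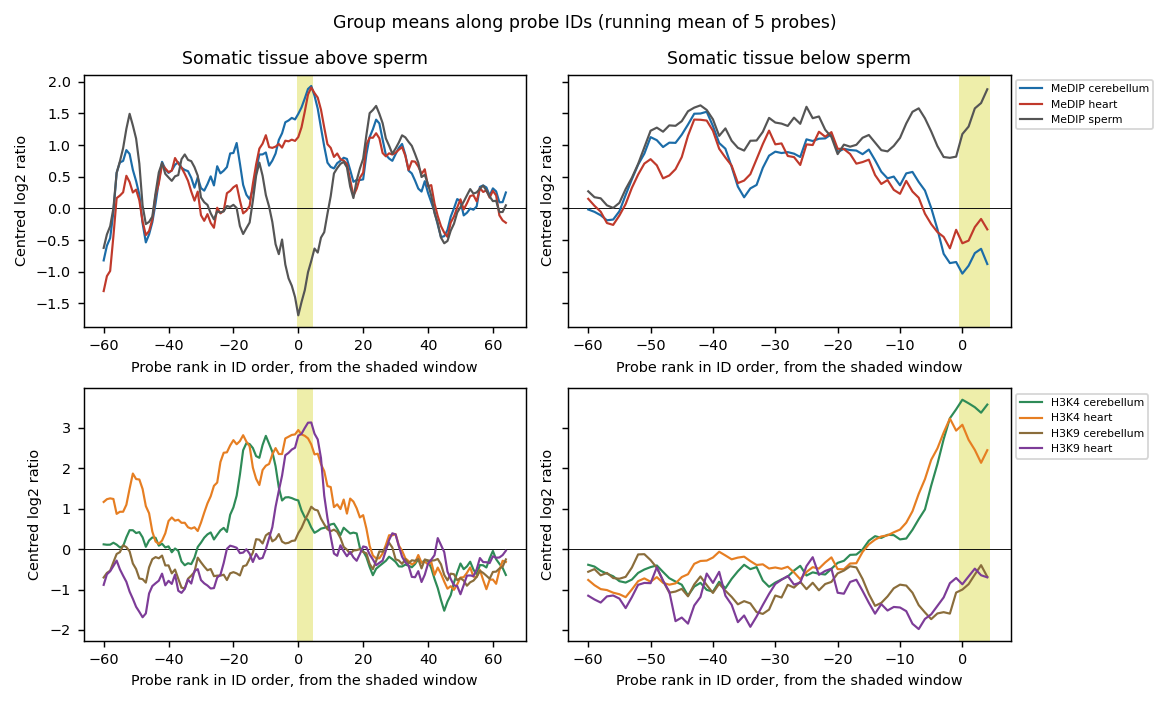
Group mean log2 ratios (y axis, running mean of 5 probes) against probe rank in ID order (x axis), for MeDIP in the upper and the histone antibodies in the lower panels, around the windows (shaded, chosen after the values were seen) with the largest higher (left, 2.92) and lower (right, -2.08) somatic minus sperm difference. Sperm MeDIP dips to a window mean of -1.29 at the left and rises to 1.58 at the right, where the block ends, and heart H3K9 has a window mean of 3.00 at the left and -0.48 at the right.

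For each tissue alone, 934 probes differed between cerebellum and sperm (729 higher, 205 lower in cerebellum) and 501 between heart and sperm (425 higher, 76 lower in heart). The named probes in cerebellum were A_68_P24333851 (3.99) and A_68_P24333850 (3.97) among the higher and A_68_P10147998 (-4.41) and A_68_P28738454 (-4.38) among the lower. In heart they were A_68_P24333850 (3.79) and A_68_P24957691 (3.74), and A_68_P28738454 (-3.87) and A_68_P31051178 (-3.77). At A_68_P24957691 the MeDIP ratio was 1.65 ± 0.15 in cerebellum, 1.65 ± 0.25 in heart and -2.09 ± 0.26 in sperm. H3K4 there was -0.63 ± 0.043 in cerebellum and, near the array median, -0.17 ± 0.018 in heart (n = 2). Both lists held 340 of the higher and 20 of the lower probes. Independent lists of these lengths would share 3.13 and 0.16, a number that ignores the shared sperm arrays. Simulated unchanged tissues shared 0 and 0 probes but also called 0 in each tissue and direction, and so set no reference for the sharing. The differences from sperm correlated across probes at 0.575 in the data and at 0.598 in the simulation, and their covariance was 0.176 against 0.126. With cerebellum set against one sperm array and heart against the other, an arrangement chosen after the data were examined, the correlation was 0.26 or 0.16 and the covariance 0.0999 or 0.065, depending on which array went to which tissue. Part of the sharing above may come from the common sperm arrays.

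On windows, cerebellum differed from sperm at 643 (457 higher, 186 lower) and heart at 278 (199 higher, 79 lower), with 164 higher and 34 lower windows in both lists. Lists were also made with a different sperm array for each tissue. Both then took their spread from the same cerebellum and heart arrays, since 1 sperm array gives none. Such lists are not independent, so no conclusion is drawn from their sharing. Scaling the arrays to one spread gave 1331 for cerebellum and 815 for heart, and in heart the majority turned to lower windows (399 higher, 416 lower). No probe passed in either tissue without sperm 1 or without sperm 2. For cerebellum against sperm 530, 224 and 580 probes passed without cerebellum 1, 2 or 3, and for heart against sperm 226 and 135 without heart 1 or 3. The window totals were 140, 102 and 331 for cerebellum without sperm 1, sperm 2 or cerebellum 2, and 80, 45 and 120 for heart without sperm 1, sperm 2 or heart 3.

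Histone ratios were then read at the windows where somatic MeDIP differed from sperm, as the design text sets DNA methylation beside histone methylation. At the 294 windows with a higher somatic ratio, H3K4 was 0.77 ± 0.22 (SD, n = 2) in cerebellum and 0.87 ± 0.18 in heart, against 0.0028 and 0.024 over all windows. H3K9 was 0.57 ± 0.20 in heart, against -0.0027 over all windows, and -0.017 ± 0.075 in cerebellum, against -0.045. The first 3 means lay outside the circular shifts (permutation p = 0.0001, the smallest they can give, adjusted p = 0.00011 over 8 tests), and the cerebellum H3K9 mean did not (permutation p = 0.75). At the 129 windows with a lower somatic ratio, H3K4 was also raised (0.46 ± 0.062 in cerebellum and 0.55 ± 0.063 in heart), but H3K9 was low (-0.46 ± 0.0087 and -0.65 ± 0.0093), each with permutation p = 0.0001. In heart, 85 of the 294 windows (28.9%) lay in the top 10% of both H3K4 and H3K9, against 4.55% of all windows (permutation p = 0.0001). In cerebellum 19 did (6.46% against 4.25%, permutation p = 0.20). The top 10% of H3K4 alone held 150 of the 294 windows in heart and 128 in cerebellum, of which these 85 and 19 were also top in H3K9. Over all windows, 757 and 708 of the 1665 top H3K4 windows were. Raised H3K4 thus adds to the joint share, and the share given H3K4 was not tested. The joint share in heart depends on the direction of the ratio, as 13 of the 294 windows (4.42%) lay in the bottom 10% of both marks, against 4.27% of all windows (permutation p = 0.96), and 5 in cerebellum (1.70% against 3.94%, permutation p = 0.089). The heart H3K9 mean was 1.05 and 1.07 at the windows called without sperm 1 or sperm 2, and the heart H3K4 mean at lower windows 0.84 without MeDIP cerebellum 2. At the 13 and 6 lower windows called without sperm 1 or sperm 2, H3K4 was 1.00 and 1.30 in cerebellum and 1.24 and 1.46 in heart, and H3K9 -0.63 and -0.52 in cerebellum and -0.84 and -0.83 in heart. Without sperm 2 the H3K9 means were no longer outside the shifts (permutation p = 0.10 and 0.078).

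**Figure D3:**
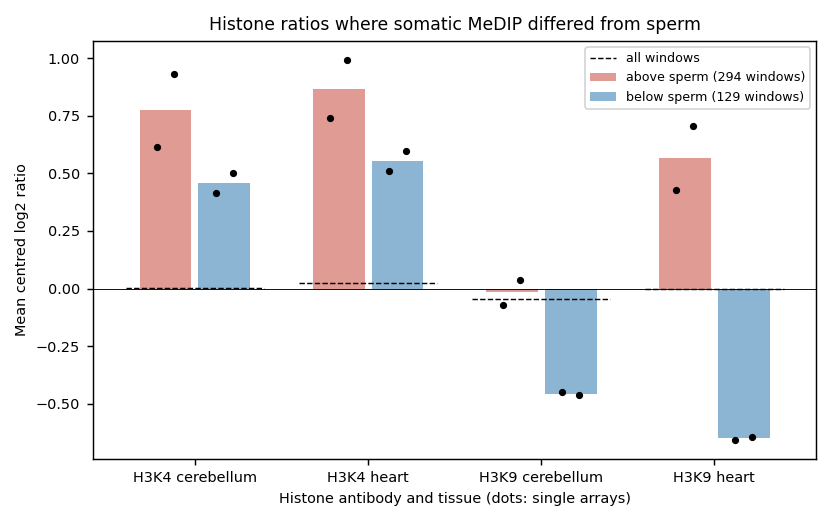
Mean centred log2 ratio (y axis) of each histone antibody and tissue at the 294 windows with a higher and the 129 with a lower somatic MeDIP ratio than sperm. Bars are means of 2 arrays, dots single arrays and dashed lines the mean of all windows. H3K9 in heart lies at 0.57 and -0.65, and H3K4 lies above 0.4 in all 4 cases.

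The heart H3K9 ratio at the 294 windows was set against what the heart H3K4 ratio gives. Over all windows H3K9 rose with H3K4 with slopes of 0.76 and 0.75 for heart H3K9 arrays 1 and 2, which gives 0.61 and 0.66 at the 294 windows against 0.43 and 0.71 measured, a difference of -0.18 on array 1 and of 0.052 on array 2. Over the 11 long blocks the means at the higher windows ranged from -0.25 (block 6, 3 windows) to 2.02 (block 1, 8 windows) for heart H3K4 and from -0.71 (block 4, 41 windows) to 2.33 (block 1) for heart H3K9. Block 3, with the most such windows (44), had 1.17 and 0.92. The H3K4 arrays were far apart in block 10 (0.39 and 1.55) and block 11 (0.81 and 2.97). The heart H3K9 arrays were also far apart in block 10 (0.42 and 1.81). Differences between blocks were not tested.

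Cerebellum and heart were compared with each other for tissue-specific MeDIP ratios. Of 16650 windows, 288 had a higher ratio in cerebellum and 47 a lower one. At the 288 windows cerebellum stood at 0.90 ± 0.17 (n = 3), heart at -0.17 ± 0.047 (n = 3) and sperm at -0.030 ± 0.053 (n = 2). At the 47 windows cerebellum stood at -0.36 ± 0.094, heart at 0.66 ± 0.16 and sperm at 0.60 ± 0.15. The 2 technical cerebellum arrays averaged 1.01 ± 0.048 and -0.29 ± 0.059 there. They were not used for the calls but repeat cerebellum material that may have been, so they are no independent check. Histone ratios were read at the same windows. At the 288 windows cerebellum minus heart was 0.49 for H3K4 (0.41 to 0.56 over single array pairs) and 0.61 for H3K9 (0.48 to 0.73), both with permutation p = 0.0001 and adjusted p = 0.0002 over 4 tests. With the arrays of each assay scaled to one spread the differences were 0.48 and 0.38. At the 47 windows it was 0.039 (permutation p = 0.53) and -0.044 (permutation p = 0.99) unscaled, and 0.068 and -0.17 scaled, where H3K9 was lower in cerebellum in each pair of arrays (-0.23 to -0.12). Whether the 2 sets of windows differ in this was not tested.

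Among single probes 188 differed between cerebellum and heart in MeDIP, 170 higher and 18 lower in cerebellum. The largest higher ratios were at A_68_P06079168 (3.26, SE 0.35, limma adjusted p = 0.017; 1.48 ± 0.32 in cerebellum and -1.78 ± 0.55 in heart) and A_68_P25600741 (3.14). At the first, H3K4 was 0.68 ± 0.14 and -1.20 ± 0.37, and H3K9 -0.18 ± 0.38 and -1.63 ± 0.13, in cerebellum and heart (n = 2). The largest lower ratios were at A_68_P06053395 (-3.03, SE 0.50, limma adjusted p = 0.048), where H3K4 was 4.52 ± 0.64 in cerebellum and 3.48 ± 0.24 in heart, and at A_68_P28737192 (-2.92), where sperm (2.25 ± 0.10) stood near heart (1.98 ± 0.42). The call of A_68_P06053395 was lost in 9 of 13 alternatives, among them each fit without an array and the values as deposited (adjusted p from 0.017 to 0.23 over the 13), and those of the other 3 probes in 5, 3 and 5. The probe split was 549 higher and 148 lower with scaled arrays and 505 and 189 with quantile normalization, and the window split 750 and 206, and 664 and 314. Without cerebellum 1, 2 or 3 the probe counts were 5, 0 and 38 and without heart 1, 2 or 3 they were 8, 26 and 0. The window totals were 75 and 192 without cerebellum 2 or 3, and 187, 191 and 43 without heart 1, 2 or 3. Only 70 probes passed on the values as deposited.

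H3K4 differed between cerebellum and heart at 672 windows, 350 higher and 322 lower in cerebellum. The window starting at A_68_P06007081, chosen after its values were seen, had the largest higher ratio (3.67, SE 0.28, limma adjusted p = 0.0010), with 3.34 ± 0.58 in cerebellum and -0.33 ± 0.21 in heart, while its H3K9 and MeDIP ratios were 0.39 and -0.79 in cerebellum. The largest lower ratio was at the window starting at A_68_P32461160 (-2.43), where heart H3K4 was 1.04 ± 0.84 and heart H3K9 1.69 ± 0.94, and its MeDIP ratio was 1.33 ± 0.34 in cerebellum, 1.32 ± 0.38 in heart and -0.13 ± 0.019 in sperm. With the replicate number as a block 1608 windows passed and most were lower (711 higher, 897 lower). Leaving out cerebellum 1, cerebellum 2, heart 1 or heart 2 gave 29, 15, 56 and 19. At single probes limma called 0, with 10833 probes at an unadjusted p under 0.05, 8 with the trended robust variance, 21 with scaled arrays and 0 with the block.

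H3K9 differed between cerebellum and heart at 1640 windows, 577 higher and 1063 lower in cerebellum. The heart H3K9 arrays differed more from each other across probes (SD of the difference 0.98) than the other ChIP pairs (0.66 to 0.75). The spread shared by the 4 groups may thus be too small for this comparison, and windows were not fitted with only the groups compared. The window starting at A_68_P28733684, also chosen after its values were seen, had the largest lower ratio (-3.28, SE 0.32, limma adjusted p = 0.0012), with -0.44 ± 0.39 in cerebellum and 2.83 ± 0.31 in heart. Its MeDIP ratio was 1.58 ± 0.58 in heart and 1.71 ± 0.19 in sperm. The largest higher ratio was at the window starting at A_68_P06099299 (2.43), with 0.28 ± 0.27 in cerebellum and -2.14 ± 0.98 in heart. The heart arrays had the wider spread (SD 1.15 and 1.16 against 0.75 and 0.75), and with equal spread 431 windows passed (98 higher, 333 lower), with quantile normalization 496 (168 higher, 328 lower) and with the replicate block 3416 (1331 higher, 2085 lower). Leaving out cerebellum 1, cerebellum 2, heart 1 or heart 2 gave 61, 114, 996 and 782. At single probes limma called 0, with 18672 at an unadjusted p under 0.05, 31 with the trended robust variance, and 908 with the block (220 higher, 688 lower). Without heart 1 or heart 2, which leaves 1 heart H3K9 array, more of the called probes were higher than lower in cerebellum. The main fit called 0 probes and gives no direction at probes. The probes called with the block and the windows of the main fit were mostly lower, so the direction of probe calls is not settled. Without heart 2 the called windows were nearly even between the directions.

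The 3 profiles were finally set against each other within each tissue. The windows in the top 10% of both H3K4 and H3K9 numbered 708 of 16650 in cerebellum and 757 in heart, 4.25 and 4.55 times the number expected of independent marks (permutation p = 0.0001 each, adjusted p = 0.0002 over 6 tests). The top MeDIP and H3K9 windows shared 53 in cerebellum, 0.32 times the expected number (permutation p = 0.0016, adjusted p = 0.0024), and 205 in heart, 1.23 times (permutation p = 0.32). The top MeDIP and H3K4 windows shared 129 in cerebellum, 0.77 times (permutation p = 0.10), and 254 in heart, 1.53 times (permutation p = 0.0001). The direction in heart depends on the share taken, as on single probes MeDIP and H3K4 were at 1.27 times in the top 10% and 0.96 times in the top 20%, and MeDIP and H3K9 at 1.02 and 0.70 times. Whether the tissues differ in these overlaps was not tested. On single probes the ratios in the top 10% were 3.89 and 4.52 for H3K4 with H3K9 in cerebellum and heart, and in cerebellum 0.55 for MeDIP with H3K9 and 0.82 for MeDIP with H3K4. The overlaps of MeDIP depend on the direction of the ratio. In the bottom 10% of windows, MeDIP and H3K4 shared 65 in cerebellum (0.39 times, permutation p = 0.0001) and 54 in heart (0.32 times, permutation p = 0.0048), below the expected number in both. MeDIP and H3K9 shared 60 in cerebellum (0.36 times, permutation p = 0.0004) and 43 in heart (0.26 times, permutation p = 0.0009). H3K4 and H3K9 stayed above it, at 3.94 and 4.27 times (permutation p = 0.0001 each), and all 6 had an adjusted p of 0.0048 or less. On single probes of the bottom 10% the ratios were 0.62 and 0.71 for MeDIP with H3K4, 0.43 and 0.52 for MeDIP with H3K9, and 3.81 and 3.72 for H3K4 with H3K9, in cerebellum and heart.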

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

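The tests of array spread and of an effect common to all assays were chosen after the results were seen. Of the 1075 probes that differed from sperm in at least 1 somatic tissue, 124 had a difference from sperm that itself differed between cerebellum and heart, by the direct test of cerebellum against heart. Cerebellum stood above heart at 111 of them and heart above cerebellum at 13. All 188 probes called between the tissues split much the same way, 170 and 18, so the split is not particular to the 124. The tests against sperm and between the tissues also used the same cerebellum and heart arrays. The 124 calls were lost without cerebellum 2 or without heart 3, where 0 probes passed between cerebellum and heart. Fewer arrays also lower the precision, so this does not show that the differences come from single arrays.

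The excess of MeDIP ratios that were higher in cerebellum than in heart could come from unequal array spread, from an input or regional effect common to all assays of a tissue, or from tissue-specific methylation. With scaled arrays the probe calls rose in both directions, from 170 and 18 to 549 and 148, and unequal spread as the whole cause is argued against, since with scaled or quantile normalized arrays at least 65.2% of the calls were higher in cerebellum, for windows also without any 1 array, above a bound of 60% set after the result was seen. A common effect cannot be told apart at either set of windows. At the 288 windows higher in cerebellum H3K4 and H3K9 were raised as well, by at least 0.41 in every pair of unscaled arrays. After scaling the mean differences there were 0.48 and 0.38. At the 47 lower windows the lowest difference was -0.11, and -0.23 after scaling, both for H3K9. The windows were picked by MeDIP, and the assays need not respond with the same size. The 10 ways to split the 6 arrays are too few for a share under 0.05: only 1 of the 10, the real one, called 188 probes (highest other 0), and only 1 of the 10 called 335 windows (highest other 0). Tissue-specific methylation stays open as an untested explanation.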

How the results depend on the processing

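Window results and their alternatives were chosen after the data were examined, and the cause of each shift was not tested unless stated. The minimum difference of 1 changed no probe count, and no named probe changed direction in 200 alternatives, in 46 of which its adjusted p was above 0.05. Counts on values as deposited moved by over 1.5 times only for cerebellum against heart (70). In the order cerebellum against heart, somatic tissues, cerebellum and heart against sperm, the probe counts were 694, 1472, 1816 and 1144 with quantile normalization, 697, 1272, 1649 and 976 with scaled arrays, and 701, 1158, 1604 and 850 with the trended robust variance. With the replicate block they were 0, 318, 315 and 168, and the window counts 135, 178, 289 and 128. Same-numbered MeDIP arrays lined up only in part (3 of 7 pairs above 0.1, -0.23 to 0.36). Cerebellum and sperm did (0.36 and 0.30) and sperm and heart did not (-0.028 and -0.057), so pairing of some samples is not excluded. With only the groups compared, cerebellum against heart gave 35 and cerebellum against sperm 545, from fewer arrays, and with the technical arrays added 829 and 1699. Leaving out 1 array gave 0 to 38, 0 to 763, 0 to 580 and 0 to 508 probes, and 43 to 296, 60 to 490, 102 to 620 and 45 to 312 windows. Window counts were 956, 1061, 1331 and 815 with scaled arrays, 978, 1035, 1406 and 753 with quantile normalization, and 198, 223, 369 and 148 in windows of 10 probes, of which there are fewer.

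H3K4 at probes gave 21 with scaled arrays, 8 with the trended robust variance and 0 to 1 without an array. H3K9 gave 908 with the replicate block, 31 with the trended robust variance and 0 to 879 without an array. The window counts were 1608 for H3K4 and 3416 for H3K9 with the block, 15 to 56 and 61 to 996 without an array, and for H3K9 431 with scaled arrays and 496 with quantile normalization. The block moved no other ChIP count over 1.5 times.

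Observed over expected overlaps in cerebellum were 0.71 to 1.02 without an array and 0.62 with the sign turned for MeDIP and H3K4. They were 0.48 to 0.67 and 0.32 on windows for MeDIP and H3K9, and 3.23 to 3.54, 4.59 (top 5%) and 2.68 (top 20%) for H3K4 and H3K9. In heart they were 1.81 (top 5%), 0.96 (top 20%), 0.71 (sign turned), 1.53 (windows) and 1.16 to 1.32 without an array for MeDIP and H3K4. For MeDIP and H3K9 they were 1.78, 0.70, 0.52, 1.23 and 0.96 to 1.05, and for H3K4 and H3K9 7.19, 2.72, 3.72 (sign turned) and 3.60 to 4.38. On windows with the sign turned, MeDIP and H3K4 were at 0.39 in cerebellum and 0.32 in heart, and MeDIP and H3K9 at 0.36 and 0.26. The overlap used group means over the probes, so no replicate block applied to it.

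With the sign turned, the share of windows higher than in sperm that were extreme in both marks was 4.42% in heart, no longer past the threshold, and 1.70% in cerebellum, below that of all windows. Of 128 alternatives for the histone means at windows that differ from sperm, 120 kept sign and side of the threshold. Of the other 8, 2 are H3K9 at the windows lower than in sperm, called without sperm 2: its range without an array was -0.63 to -0.44 in cerebellum and -0.84 to -0.60 in heart. The rest concern cerebellum H3K9 at the higher windows, not past the threshold in any: 0.0025 for the other IDs only, 0.024 with the replicate block, and -0.070 to 0.036 without an array (0.036 without H3K9 cerebellum 1, 0.0034 without MeDIP cerebellum 2, 0.036 and 0.029 without sperm 1 or 2). With the MeDIP numbers, which line up only in part, as a block in calling the windows, heart H3K9 at higher windows was 0.88. H3K4 at lower windows was then 1.06 in heart and 0.68 in cerebellum. Means over genes and regions and all their alternatives were not run, for want of positions, nor was the filter on missing values, since none was missing. Somatic tissues against sperm already uses all groups, and centring cannot change ranks, so these gave no further value.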

Other observations

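All tests here were chosen after the data were examined, and only for the matched windows and the scaled H3K9 arrays were the bounds set before the values they apply to were seen. At the windows with a lower MeDIP ratio in the somatic tissues than in sperm, 1 of 129 lay in the top 10% of both histone marks in cerebellum and 1 in heart (0.78% each, permutation p = 0.081 and 0.088), which does not pass 0.05. With the sign turned, 4 of 129 lay in the bottom 10% of both marks in each tissue (3.10%, permutation p = 0.65 and 0.73).

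A hypothesis is that heart H3K9 is raised at the windows with a higher somatic than sperm MeDIP ratio. For a probe response shared by all arrays, uncalled windows were matched on somatic MeDIP ratio. They had heart H3K9 of -0.31 and -0.20, and the called windows exceeded them by at least 0.74. Heart H3K4 differed as well (0.87 called, -0.024 matched), and so did sperm MeDIP (-0.57 and 0.79). This argues only against a response that follows the somatic MeDIP ratio, since the windows were not matched on how their probes respond in ChIP. The wider spread of the heart H3K9 arrays is argued against as the whole cause, since after scaling heart exceeded cerebellum by at least 0.31 in each of the 4 pairs of arrays. An H3K9 ratio that only follows the H3K4 ratio stays open, because the excess over the regression on H3K4 was 0.052 on heart array 2 but -0.18 on heart array 1, so that the arrays lay on opposite sides of the regression. The lower windows, with raised H3K4 and H3K9 of -0.65 in heart, show that following H3K4 does not hold everywhere, and a difference between the tissues stays open.

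H3K4 and H3K9 ratios rose and fell together. Chromatin or input shared by same-numbered arrays of one tissue is argued against as the whole cause, because arrays of another tissue and another number still correlated at 0.21 or more across probes, although the mean r was 0.28 there against 0.46 for the same tissue and number. For a probe response shared by all 3 assays, MeDIP arrays were correlated with histone arrays. Of 64 pairs 63 were negative, from -0.30 to a highest value of 0.0090. A shared response alone would not give this. It could be masked by an opposite relation between the assays, so it is not excluded. A response common to the ChIP arrays alone, cross-reaction of the antibodies and real co-occurrence of the marks stay open, and none was tested.

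The technical cerebellum arrays correlated best with cerebellum 2 (0.87 and 0.85, against 0.77 to 0.80 for cerebellum 1 and 3), and with each other at 0.88. Heart H3K9 array 1 had 89 probes with a ratio beyond 8 in size, 82 of them negative. Over all 89, array 2 averaged -0.026. These values were kept in the heart H3K9 means and fits. The long ID blocks minus other IDs gave 0.046 ± 0.025 and 0.085 ± 0.027 for H3K9 in cerebellum and heart, 0.021 ± 0.019 and 0.045 ± 0.026 for H3K4 (n = 2 each), and -0.043 ± 0.0062, -0.019 ± 0.017 (n = 3 each) and -0.048 ± 0.0030 (n = 2) for MeDIP in cerebellum, heart and sperm.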
